A study of Mus musculus with 9 samples.

How the data were processed

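Gene expression was measured in 9 mouse samples, each on 1 single-colour Agilent 8x60K mouse gene expression array. Per the labels, total RNA was extracted with TRIzol and 200 ng of it were labelled with Cy3. Groups were taken from the labels: 3 samples of glioma tissue with EZH2 knocked out, 2 of glioma cells of the MADM mouse background, 2 of astrocytes and 2 of neural stem cells. The labels do not say whether samples of a group came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical. Sex-linked transcripts set tissue array 1 apart from the other tissue arrays and the astrocyte arrays apart from each other, as given below.

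The deposited scanner files hold the intensity of each spot on a linear scale. Per the file headers they were written by Agilent Feature Extraction, version 10.7.3.1 for the 3 tissue arrays and version 10.7.1.1 for the 6 cell arrays, while the submitters' processing notes name version 10.7.3.1. Per the file headers, background subtraction and spatial detrending were applied within each array, and processed signals were not scaled between arrays, as their 75th percentiles differ. A deposited table of log2 values, by the authors, came with the same arrays. Set against the scanner files, 99.01% to 99.81% of its values on an array lay within 0.01 of the log2 processed signal with no scaling between arrays. Its column medians ran from 5.08 to 6.28, and its centring and scale were settled by that match. It was used as an alternative only.

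Each array had 62976 spots, of which 59305 were not controls. Spots flagged as outliers, 96 to 164 per array, were left out, and spots of 1 probe were averaged. Of 55681 probes, 15 had no spot left on an array and 55666 were kept. No spot was saturated. Gene names came from the accession for 27226 probes, from the symbol for 3584 and from a synonym for 565, through a RefSeq gene table of GRCm38.p6 used for names only. The other 24291 probes kept the name in the file. Probe positions are those of the files, in mm9.

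The values analysed were log2 of the processed signal minus the 75th percentile of each array over the non-control probes. A probe was tested if it was well above background on every array of at least 1 group in the fit, and a gene was represented by its brightest tested probe. Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. The glioma cells, astrocytes and neural stem cells were compared with each other in 1 fit of the 6 cell arrays, with 3 residual degrees of freedom. The tissue was compared with the glioma cells in a fit of all 9 arrays, with 5 residual degrees of freedom. Where a gene was not well above background on any array of 1 side, the change is given as a bound. The mean of the brighter group was set against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the gene's own signal. List medians use the fitted changes, and where values below that lowest signal moved a printed median, it is also given with them raised to it. Ranges with 1 array left out come from fits that leave out each array in turn.

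There were 23 gene lists, fixed before the data were examined: markers of oligodendrocyte precursors, mature oligodendrocytes, astrocytes, neural stem cells and radial glia, neurons, microglia and macrophages, lymphocytes, endothelium and pericytes, and fibroblasts and meninges, red blood cell transcripts, cell cycle genes, Polycomb and H3K27 demethylase genes, Hox genes, other Polycomb targets, p53 targets, RAS-MAPK output genes, mesenchymal glioma genes, antigen presentation genes, interferon-stimulated genes, hypoxia and glycolysis genes, cholesterol synthesis genes, immediate early and heat shock genes, and sex-linked transcripts. Lists with at least 4 tested members were compared with all other genes by limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of a comparison. The red blood cell list had too few tested members for that test. No list shift was called with the estimated correlation in any comparison.

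The rule for named genes was also fixed beforehand. It takes Ezh2, Trp53, Nf1 and Pdgfra, the 5 largest rises and falls among characterised genes measured on both sides with no overlap of arrays, the 3 largest bounds in each direction, and up to 2 called members per list and direction, or members that did not pass where none did. Among genes called against both normal cell types it takes the 5 in each direction with the largest smaller fold. The text gives a part of these, and some named genes are not reported here.

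The fits were tested on simulated arrays with the real means and spread and 200 changed genes per comparison. For glioma cells against astrocytes, 2% of genes changed by 2 on the log2 scale were recovered, 52% of those changed by 3 and 80% of those changed by 4. For glioma cells against neural stem cells the shares were 4%, 46% and 74%. For neural stem cells against astrocytes they were 4%, 42% and 84%. For tissue against glioma cells they were 40%, 84% and 92%. No gene changed by 1 was recovered in any of the 4 comparisons. The simulated fits called 72, 66, 68 and 115 genes in this order, and the real fits 4688, 244, 3633 and 4298. The adjusted p depends on how many genes change, so these shares hold for 200 changed genes only. They do not give the recovery of the real fits, where Idi1 was called at 2.28 for glioma cells against astrocytes.

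Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' unscaled table, no filter and a stricter filter on dim probes, the mean over a gene's probes, no minimum fold, an intensity trend with robust variances, other arrays in the fit, the replicate number as a block, and leaving out each array in turn. For the tissue arrays the mean spot signal was not used here, and normexp took the median spot signal in the 9-array fit.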

Results

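Transcript levels were compared between mouse gliomas and normal brain cells on 9 single-colour microarrays. Mosaic analysis with double markers (MADM) is a mouse genetic method in which recombination between chromosomes makes rare marked mutant cells. Glioma cells of this background were measured on 2 arrays, brain tumour tissue with EZH2 knocked out on 3, and astrocytes and neural stem cells of normal wild-type C57BL/6J brain on 2 each. Between 60.1% and 65.7% of spots were well above background on an array, and the 75th percentile of signal lay between 467 and 1015 intensity units. The number of arrays limits the precision. Replicate arrays differed by a root mean square of 0.88 (mean of the tissue pairs), 1.03 (glioma cells), 0.99 (astrocytes) and 1.01 (neural stem cells) on the log2 scale. Glioma cells differed from neural stem cells by 1.38, from astrocytes by 2.10 and from the tissue by 1.72.

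**Figure D1:**
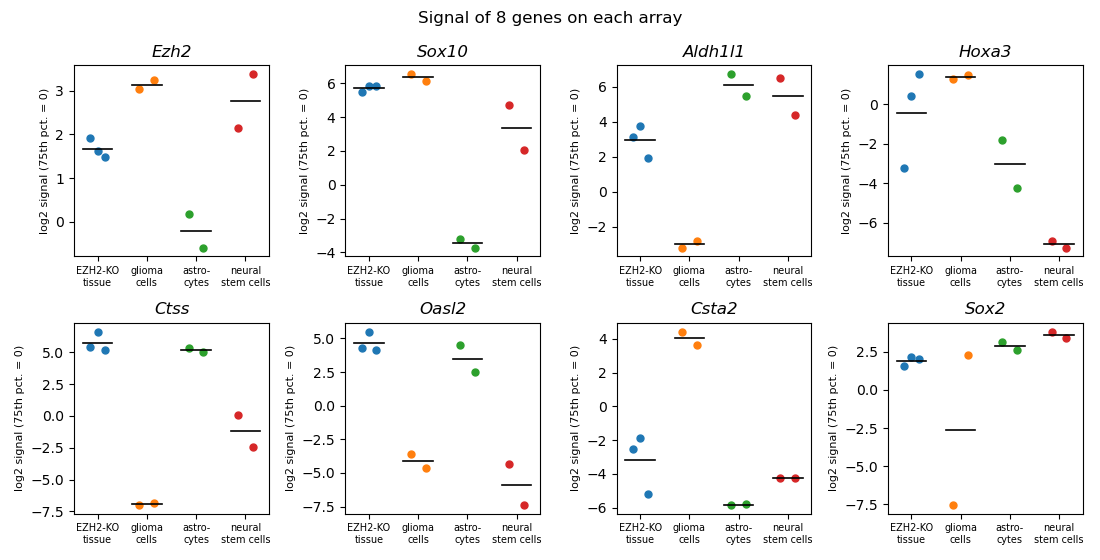
Normalised log2 signal of 8 genes on each array, where 0 is the 75th percentile of the array, points are arrays and lines are group means. Sox10 lies high in the glioma cells and the tissue, and Aldh1l1 is lowest in the glioma cells. Sox2 reads -7.55 on 1 glioma cell array, where it is not well above background, and 2.28 on the other.

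Glioma cells were first set against astrocytes, a mature glial cell type. Markers of oligodendrocyte precursors stood far higher in the tumour cells: Sox10, a transcription factor of the oligodendrocyte lineage, was 882-fold higher (log2 fold change 9.79, SE 0.88, limma adjusted p = 0.0040), and Gpr17, a receptor of oligodendrocyte precursors, was at least 4773-fold higher. Astrocyte and myeloid transcripts stood far lower. Aldh1l1, a folate enzyme used as an astrocyte marker, was 553-fold lower (log2 fold change -9.11, SE 0.82, adjusted p = 0.0039), and Ctss, a lysosomal protease of myeloid cells, was at least 1254-fold lower. Ezh2, the histone H3K27 methyltransferase of Polycomb complex PRC2, was 10.1-fold higher in glioma cells (log2 fold change 3.33, SE 0.52, adjusted p = 0.0150). Its call was lost without either glioma cell array or astrocyte array 2 (adjusted p up to 0.0698). Aldh1l1 ran from -9.75 to -8.47 with 1 array left out, and the bound of Gpr17 from 1941-fold to 11735-fold.

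Of 16 oligodendrocyte precursor markers, 9 rose in glioma cells relative to astrocytes and none fell (14 adjusted over the list alone), Lhfpl3 by 7.56 on the log2 scale, with a camera adjusted p of 9.18e-07 (adjusted p = 0.471 with an estimated correlation). Pdgfra, a receptor on precursor cells, had a log2 fold change of 2.59 (SE 0.71, adjusted p = 0.0604) and did not pass. Cell cycle genes rose, 9 of 22 by the call (19 adjusted over the list alone), among them Ccnb1, a mitotic cyclin, by 37.2-fold and Top2a, a topoisomerase of dividing cells, by 34.7-fold (camera adjusted p = 6.42e-06, or adjusted p = 0.539 with an estimated correlation). Hox genes had 6 of 17 members higher, such as Hoxd8 with a log2 fold change of 6.73 (well above background on 1 of 2 astrocyte arrays), and 1 lower, Hoxb4 (camera adjusted p = 0.0179, or adjusted p = 0.539 with an estimated correlation). Polycomb genes had 3 of 20 members higher, among them Cbx2 with 3.66 (camera adjusted p = 0.0115, or adjusted p = 0.471 with an estimated correlation). Cholesterol synthesis genes had 2 of 16 higher, among them Idi1 with 2.28 (6 adjusted over the list alone; camera adjusted p = 0.0072, or adjusted p = 0.539 with an estimated correlation). Lhfpl3 ran from 6.24 to 8.88 with 1 array left out and Hoxd8 from 5.37 to 8.09, and the call of Hoxd8 was lost without astrocyte array 1 (adjusted p = 0.0702). Those of Ccnb1, Top2a and Idi1 were lost with each glioma cell or astrocyte array left out in turn (adjusted p up to 0.121, 0.143 and 0.132).

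Microglia and macrophage markers fell in glioma cells relative to astrocytes, with 15 of 16 members lower and a median log2 fold change of -5.73 (camera adjusted p = 4.85e-11, or adjusted p = 0.471 with an estimated correlation). The mean level of that list was 3.01 and 3.53 on the astrocyte arrays and -3.87 and -3.67 on the glioma cell arrays. Interferon-stimulated genes fell in 12 of 17 (13 adjusted over the list alone), Oas1a by 507-fold and Ifit1 by at least 234-fold (camera adjusted p = 1.91e-08, or adjusted p = 0.539 with an estimated correlation). Mesenchymal glioma genes fell in 9 of 16 (14 adjusted over the list alone), among them Anxa1 by 370-fold and Osmr, the oncostatin M receptor, by at least 1013-fold (camera adjusted p = 1.91e-08, or adjusted p = 0.471 with an estimated correlation). Astrocyte markers fell in 8 of 16, such as Gja1, a gap junction protein, by at least 96.9-fold (camera adjusted p = 1.87e-04, or adjusted p = 0.539 with an estimated correlation). Fibroblast and meningeal markers fell in 5 of 11, among them Acta2 by 507-fold (camera adjusted p = 2.53e-04, or adjusted p = 0.539 with an estimated correlation), and their mean level was 0.40 on astrocyte array 1 and 4.58 on astrocyte array 2. Of p53 target genes 6 of 16 were lower (9 adjusted over the list alone), such as Phlda3 (camera adjusted p = 5.24e-05), and of antigen presentation genes 6 of 12, such as H2-K1 (camera adjusted p = 0.0072); for both, adjusted p = 0.539 with an estimated correlation. Immediate early genes were lower in 4 of 11, Junb by 30.7-fold (camera adjusted p = 0.0179, or adjusted p = 0.539 with an estimated correlation), and this shift was lost without glioma cell array 2 (adjusted p = 0.0542) or astrocyte array 1 (adjusted p = 0.112). Oas1a and Junb were well above background on 1 of the 2 glioma cell arrays. With 1 array left out, log2 fold changes ran from -10.41 to -6.65 (Anxa1, SE 1.54), -10.63 to -7.34 (Acta2), -10.26 to -7.71 (Oas1a) and -5.88 to -4.00 (Junb), and the bound of Gja1 from 59.7-fold to 157-fold. The call of Anxa1 was lost without glioma cell array 2 or astrocyte array 2 (adjusted p up to 0.0840) and that of Junb without either astrocyte array (up to 0.0772). That of Phlda3 was lost with each of the 4 arrays left out in turn (up to 0.0908). No shift was called for mature oligodendrocyte (camera adjusted p = 0.235), neural stem cell (0.166), neuron (0.235), endothelial (0.0873), RAS-MAPK (0.356), hypoxia (0.139) or other Polycomb target genes (0.481). No lymphocyte or sex-linked member was called, with Lck at -0.87.

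In all, 4688 of 24868 genes were called between glioma cells and astrocytes with limma, 2240 higher and 2448 lower in glioma cells. The arrays of the groups did not overlap for 69.2% of genes, where chance gives 33.3%. On the unscaled table the higher share of calls was 30.0% in place of 47.8%. The count was 2306 without glioma cell array 1, 2052 without glioma cell array 2, 2001 without astrocyte array 1 and 1987 without astrocyte array 2.

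Glioma cells lay closer to neural stem cells, the self-renewing precursors of neurons and glia, and 244 genes were called. Developmental regulators were higher in glioma cells: Hoxa3 by at least 104-fold (adjusted p = 0.0260) and Foxf1, a forkhead factor of mesoderm, by at least 255-fold (adjusted p = 0.0251). Csta2, a stefin family protease inhibitor, was 311-fold higher (log2 fold change 8.28, SE 0.35, adjusted p = 0.0114). Aldh1l1 was 354-fold lower (log2 fold change -8.47, SE 0.82, adjusted p = 0.0288), and Slc6a11, a GABA transporter of astrocytes, at least 178-fold lower. Ezh2 (log2 fold change 0.37, SE 0.52, adjusted p = 0.813) and Pdgfra (1.01, SE 0.71, adjusted p = 0.602) did not pass. Aldh1l1 ran from -9.54 to -7.39 with 1 array left out and the bound of Slc6a11 from 85.3-fold to 373-fold. The calls of Hoxa3, Foxf1, Csta2, Aldh1l1 and Slc6a11 were each lost without glioma cell array 1 or either neural stem cell array (adjusted p up to 0.134).

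Hox genes shifted upward in glioma cells relative to neural stem cells, 5 of 17 by the call (9 adjusted over the list alone; median log2 fold change 4.67, or 4.03 with values below the floor raised to it, as 13 members were not well above background on any array of at least 1 of the groups; camera adjusted p = 1.30e-10, or adjusted p = 0.486 with an estimated correlation). Other Polycomb targets followed with 3 of 20 higher (10 adjusted over the list alone; camera adjusted p = 3.56e-08, or adjusted p = 0.486 with an estimated correlation). Astrocyte markers had 2 of 16 lower, Aldh1l1 and Gja1 (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0029, or adjusted p = 0.615 with an estimated correlation), and the shift was lost without neural stem cell array 1 (adjusted p = 0.755). The mean level of astrocyte markers was 3.86 on that array and 0.70 on neural stem cell array 2. Several lists had a camera shift with no called member: antigen presentation genes upward (median 1.61, camera adjusted p = 1.76e-05, 6 adjusted over the list alone) and Polycomb genes upward (median 0.35, camera adjusted p = 0.0399), both with adjusted p = 0.486 with an estimated correlation. Microglia markers (median -1.17, camera adjusted p = 1.78e-04), p53 targets (-0.96, 0.0030) and cholesterol genes (-0.65, 0.0063) shifted downward and oligodendrocyte precursor markers (0.88, 0.0101) upward, all with adjusted p = 0.615 with an estimated correlation. Of the 16 microglia markers, 7 were lower adjusted over the list alone. Likewise 7 of the 16 were not well above background on any array of at least 1 of the groups. Stem cell markers shifted downward (median -1.45, camera adjusted p = 4.09e-04, or adjusted p = 0.531 with an estimated correlation), with 5 adjusted over the list alone. Cell cycle genes had a median of 1.27 (camera adjusted p = 0.0029, or adjusted p = 0.615 with an estimated correlation) and of -0.27 without neural stem cell array 1, where their mean level was 1.24 against 4.25 on neural stem cell array 2. Without 1 array the camera adjusted p rose to 0.0683 (glioma cell array 1) and 0.447 (neural stem cell array 2) for precursor markers, and to 0.124 for p53 targets and 0.217 for cholesterol genes without neural stem cell array 2. For Polycomb genes it rose to 0.0683, 0.0933 and 0.146 without glioma cell array 1, glioma cell array 2 and neural stem cell array 1, and to 0.0516 with quantile normalization, and for microglia markers to 0.136 with the stricter filter. Endothelial markers had a median of 0.24 and a mean of -0.21, and lymphocyte markers a median of -0.07 and a mean of 0.02, both upward by camera and not called (camera adjusted p = 0.753 and 0.981). With values raised to the floor the endothelial median was 0.17.

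Of the 244 genes called by limma between glioma cells and neural stem cells, out of 24868, 165 were higher and 79 lower in glioma cells, and 46.0% of genes had no overlap of arrays against 33.3% by chance. The count rested on single arrays: it was 0 without glioma cell array 1 or without neural stem cell array 1 (2783 and 3463 genes at an unadjusted p under 0.05), 4 without neural stem cell array 2 and 28 without either astrocyte array, which share the estimate of spread.

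Genes that set glioma cells apart from both normal cell types were then counted. There were 135 genes higher and 61 lower than in both, where independent lists of these sizes would share 14.9 and 7.78. Simulated glioma groups with no effect gave 0 in each of 100 draws. That value leaves out the real effects and so sets no level for lists of this size. Part of the excess may come from the shared glioma arrays. Pou4f1, a POU homeobox factor of sensory neurons, was 81.8-fold above astrocytes and 50.9-fold above neural stem cells. Bricd5 was 506-fold and 72.8-fold higher and the olfactory receptor gene Olfr1466 was 56.5-fold and 60.2-fold higher. Hoxa3, Hoxa4, Hoxa5, Hoxd13, Barx1 and Foxf1 were the members of the Polycomb target lists above both. Aldh1l1 was 553-fold and 354-fold lower, Lamb2, a laminin chain, 468-fold and 61.3-fold lower, and Igfbp2, a binding protein of insulin-like growth factors, 69.9-fold and 28.9-fold lower. The count of higher genes was 0 without glioma cell array 1 or neural stem cell array 1, 4 without neural stem cell array 2, 84 without glioma cell array 2, and 17 and 20 without astrocyte array 1 and 2. That of lower genes was 0 without glioma cell array 1 or either neural stem cell array, and 6 and 3 without astrocyte array 1 and 2. Bricd5 ran, with 1 array left out, from 7.72 to 10.24 on the log2 scale against astrocytes and 4.92 to 7.45 against neural stem cells, Igfbp2 from -6.82 to -5.43 and -5.54 to -4.16, and Aldh1l1 from -9.75 to -8.47 and -9.54 to -7.39.

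Neural stem cells compared with astrocytes gave the contrast between the samples of the normal cell types. RNA of other cells in the astrocyte samples, a candidate given below, was not taken off. Neural stem cells had higher Sox3, a transcription factor of neural progenitors (242-fold; log2 fold change 7.92, adjusted p = 0.0143). Hes5, a Notch effector, was also higher (191-fold; 7.58, SE 1.41, adjusted p = 0.0287). Sox10 was 112-fold higher and Gpr17 at least 2557-fold higher. Ifi27l2a, an interferon-induced gene, was 919-fold lower (log2 fold change -9.84, SE 1.46, adjusted p = 0.0166), and Ogn, a matrix proteoglycan of connective tissue, at least 467-fold lower. Ezh2 was 7.77-fold higher in neural stem cells (log2 fold change 2.96, SE 0.52, adjusted p = 0.0247). Log2 fold changes with 1 array left out ran from 6.21 to 9.62 (Sox3), 5.67 to 9.49 (Hes5), 5.47 to 8.15 (Sox10), -11.73 to -7.96 (Ifi27l2a) and 2.34 to 3.58 (Ezh2). Bounds ran from 743-fold to 8803-fold (Gpr17) and 268-fold to 813-fold (Ogn). Calls were lost without either neural stem cell array for Sox3 and Ifi27l2a (adjusted p up to 0.0799 and 0.0896), without either or astrocyte array 2 for Hes5 (0.0876), without either astrocyte array for Sox10 (0.0620), and without either of these or neural stem cell array 2 for Ezh2 (0.104).

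Precursor markers rose in 10 of 16 in neural stem cells relative to astrocytes (11 adjusted over the list alone; camera adjusted p = 3.01e-05, or adjusted p = 0.365 with an estimated correlation), with Sox10 at 6.81. Cholesterol synthesis genes rose in 8 of 16 (12 adjusted over the list alone; camera adjusted p = 3.01e-05, or adjusted p = 0.469 with an estimated correlation), Cyp51 by 12.4-fold. Neuron markers had 5 members higher, such as Dcx, a microtubule protein of young neurons, by at least 92.2-fold (camera adjusted p = 0.0496, or adjusted p = 0.507 with an estimated correlation). This shift was lost with normexp (adjusted p = 0.0929), the stricter filter (0.247), and without astrocyte array 2 (0.0932) or neural stem cell array 1 (0.152). Cell cycle genes had a median of 2.59 with no called member (camera adjusted p = 4.89e-04, or adjusted p = 0.558 with an estimated correlation), and Mki67 stood at 3.88 (adjusted p = 0.0592). Microglia markers fell in 14 of 16 (15 adjusted over the list alone; camera adjusted p = 3.45e-10), interferon-stimulated genes in 12 of 17 (16 adjusted over the list alone; 4.23e-11), mesenchymal genes in 12 of 16 (15 adjusted over the list alone; 1.00e-09), other Polycomb targets in 10 of 20 (13 adjusted over the list alone; 2.00e-06) and antigen presentation genes in 7 of 12 (8 adjusted over the list alone; 1.80e-06), all with adjusted p = 0.365 with an estimated correlation. Examples are C1qa, a complement component, at -6.91, Oasl2 at -9.35 (well above background on 1 of 2 neural stem cell arrays), Irx3, a homeobox factor among the Polycomb targets, at -6.09 and Psmb8, an immunoproteasome subunit, at -6.67. The mean microglia marker level was -0.54 and -2.22 on the neural stem cell arrays against 3.01 and 3.53 on the astrocyte arrays. Fibroblast markers had 2 lower (4 adjusted over the list alone; camera adjusted p = 9.96e-04), immediate early genes 4 lower (6 adjusted over the list alone; 0.0012) and endothelial markers 2 lower (0.0193), all with adjusted p = 0.469 with an estimated correlation, and fibroblast marker levels were 0.40 and 4.58 on the astrocyte arrays. The endothelial shift was lost without astrocyte array 2 (adjusted p = 0.151) and with the stricter filter (0.0662). Hox genes had 3 lower (4 adjusted over the list alone; camera adjusted p = 0.0065, or adjusted p = 0.501 with an estimated correlation), a shift lost with normexp, where the median was 0.087 in place of -0.56 (-0.34 with values raised to the floor; adjusted p = 0.207), and with no filter (0.0687). Astrocyte markers (camera adjusted p = 0.0185) and p53 targets (0.0044) had medians of -0.83 and -1.06 with no called member, both with adjusted p = 0.558 with an estimated correlation. The first was lost without astrocyte array 1 (adjusted p = 0.164) or neural stem cell array 2 (0.415, median 0.29) or on the unscaled table (0.0736), and the second without astrocyte array 2 (0.0774) or neural stem cell array 1 (0.145). The ranges of log2 fold changes with 1 array left out were -8.80 to -5.02 (C1qa), -10.87 to -7.82 (Oasl2), -7.79 to -5.55 (Psmb8), 5.47 to 8.15 (Sox10) and 2.54 to 4.73 (Cyp51), and the bound of Dcx from 29.1-fold to 292-fold. Calls were lost without either astrocyte array for C1qa, Dcx and Sox10 (adjusted p up to 0.105, 0.0770 and 0.0620), without astrocyte array 1 for Oasl2 (0.0501), without neural stem cell array 2 for Psmb8 (0.0711) and with each array except astrocyte array 2 left out in turn for Cyp51. Gfap (log2 fold change -5.63, adjusted p = 0.0575) and Aqp4 (-5.81, adjusted p = 0.0501) did not pass.

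By limma, 3633 of 24868 genes were called, 1680 higher and 1953 lower in neural stem cells, and 66.3% of genes had no overlap of arrays against 33.3% by chance. On the unscaled table the higher share was 24.1% in place of 46.2%. The count was 1493 and 1265 without astrocyte array 1 and 2, and 1197 without neural stem cell array 2.

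**Figure D2:**
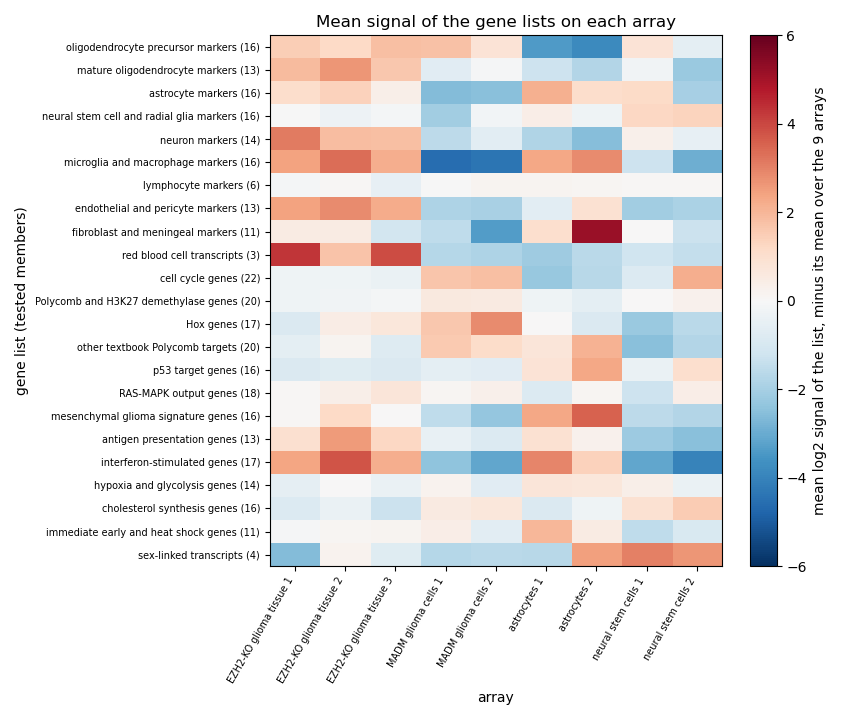
Mean normalised log2 signal of the tested members of each gene list on each array, minus the mean of the list over the 9 arrays, as a colour scale from blue (lower) to red (higher). Microglia and macrophage markers stand at 3.13, 4.04 and 2.90 (before the mean is taken off) in the tissue and at -3.87 and -3.67 in the glioma cells.

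In the knockout comparison, Ezh2 itself was at 1.91, 1.62 and 1.48 on the EZH2-KO tissue arrays and at 3.03 and 3.24 on the glioma cell arrays, on the normalised log2 scale. It was at 0.19 and -0.58 in astrocytes and 2.14 and 3.38 in neural stem cells. The difference between tissue and glioma cells, -1.46 (SE 0.42, adjusted p = 0.0502), did not pass. The Ezh2 probe lies at chromosome 6, 47480307 to 47480366 (mm9), and the labels do not give the deleted part, so a probe outside it would check nothing. Each tissue array came from slide 1 and scan 1 and each cell array from slide 2 and scan 2. Per the file headers, the extraction protocol was GE1_107_Sep09 for the tissue arrays and GE1_1105_Oct12 for the cell arrays. Slide, extraction, tissue and genotype therefore cannot be told apart in what follows.

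Interferon-stimulated genes and transcripts of microglia, vessels, neurons and red blood cells were far higher in the EZH2-KO tissue than in the glioma cells. Ctss was at least 1870-fold higher and C1qc, a complement component of microglia, at least 939-fold higher. Oasl2, an interferon-stimulated gene, was 442-fold higher (log2 fold change 8.79, SE 0.98, adjusted p = 0.0017), Cck, a neuropeptide, 325-fold higher (8.34, SE 1.01, adjusted p = 0.0025) and Cldn5, a tight junction protein of endothelium, at least 261-fold higher. Csta2 was 151-fold lower (log2 fold change -7.24, SE 0.87, adjusted p = 0.0024) and Stfa2l1, of the same stefin family, at least 59.8-fold lower. Cck ran from 7.17 to 9.51 with 1 array left out and Csta2 from -7.89 to -6.24.

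Microglia markers rose in 14 of 16 in the tissue (15 adjusted over the list alone; median 6.34, or 6.19 with values raised to the floor; camera adjusted p = 3.79e-16), interferon-stimulated genes in 13 of 17 (16 adjusted over the list alone; 1.53e-13) and endothelial markers in 9 of 13 (10 adjusted over the list alone; 1.36e-08), all with adjusted p = 0.272 with an estimated correlation. Oas1a was at 9.61 and Ly6c1 at 8.84. Neuron markers rose in 6 of 14 (10 adjusted over the list alone; camera adjusted p = 1.28e-05), among them Slc32a1, the vesicular GABA transporter, by 472-fold. Antigen presentation genes rose in 5 of 13 (9 adjusted over the list alone; 3.88e-06), such as H2-D1 by 15.5-fold, mesenchymal genes in 5 of 16 (7 adjusted over the list alone; 9.98e-05), such as Lgals3 by 14.6-fold, and mature oligodendrocyte markers in 3 of 13 (5 adjusted over the list alone; 8.71e-04), such as Mobp, a myelin protein, by at least 147-fold. For these lists, from neuron to mature oligodendrocyte, adjusted p = 0.350 with an estimated correlation. Astrocyte markers rose in 8 of 16 (9 adjusted over the list alone; camera adjusted p = 3.30e-05, or adjusted p = 0.406 with an estimated correlation), Gjb6 by at least 62.0-fold. Of fibroblast markers, 1 rose, Acta2 (camera adjusted p = 0.0067, or adjusted p = 0.433 with an estimated correlation), and the shift was lost without glioma cell array 2 (adjusted p = 0.111) and on the unscaled table (0.0616). The endothelial shift was lost with the stricter filter (adjusted p = 0.0555). No shift was called for lymphocyte markers, with 0 of 6 higher and 2 lower (median -0.16, camera adjusted p = 0.891). Adjusted over the list alone, 1 of them was higher and 2 lower. Oligodendrocyte precursor markers did not shift either, with 0 of 16 called (median -0.06, camera adjusted p = 0.691). Among red blood cell transcripts Hba-a1 was 193-fold and Hbb-b2 at least 38.6-fold higher, with Hba-a1 at 4.20, 0.53 and 3.72 on the tissue arrays. Oas1a, Ly6c1, Slc32a1 and Hba-a1 were well above background on 1 of the 2 glioma cell arrays. With 1 array left out, log2 fold changes ran from 8.33 to 10.88 (Oas1a), 8.01 to 9.67 (Ly6c1), 6.37 to 11.39 (Slc32a1), 6.90 to 8.73 (Hba-a1) and 2.80 to 4.52 (Lgals3). Bounds ran from 93.5-fold to 244-fold (Mobp), 43.9-fold to 104-fold (Gjb6) and 23.7-fold to 86.1-fold (Hbb-b2). Calls were lost without tissue array 1 or either glioma cell array for Lgals3, and without these or tissue array 2 for Acta2 (adjusted p up to 0.171).

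Cholesterol synthesis genes fell in 7 of 16 in the tissue (12 adjusted over the list alone; camera adjusted p = 4.37e-05, or adjusted p = 0.406 with an estimated correlation), such as Idi1 by 4.90-fold. Cell cycle genes fell in 2 of 22, Cdk1 and Aurkb (median -1.96, or -1.95 with values raised to the floor; camera adjusted p = 1.41e-04, or adjusted p = 0.584 with an estimated correlation). Polycomb genes fell in 3 of 20 (4 adjusted over the list alone; camera adjusted p = 0.0215, or adjusted p = 0.272 with an estimated correlation), among them Cbx8 by 8.71-fold and Cbx2 by 4.93-fold, both subunits of PRC1. That shift was lost with quantile normalization (adjusted p = 0.0770), normexp (0.0521) and the stricter filter (0.0517). Hox genes fell in 5 of 17 (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0180, or adjusted p = 0.433 with an estimated correlation), Hoxd8 by 42.2-fold (well above background on 2 of 3 tissue arrays), and this was lost without tissue array 1 (adjusted p = 0.0982) or glioma cell array 2 (0.0854). The p53 targets had a median of -0.08 (-0.18 with values raised to the floor), with an upward direction by camera that was not called (camera adjusted p = 0.942). Other Polycomb targets had 3 lower, with Barx1 at least 16.6-fold lower. Nf1, a negative regulator of RAS, was 2.08-fold lower (log2 fold change -1.06, SE 0.26, adjusted p = 0.0330), and Trp53 did not pass (-0.09, SE 0.42). Hoxd8 ran from -6.76 to -4.04 with 1 array left out. Calls were lost without glioma cell array 2 for Hoxd8 and Idi1 (adjusted p = 0.113 and 0.0653), without glioma cell array 1 for Cbx2 (0.0690), and with each tissue or glioma cell array left out in turn for Cdk1, Aurkb and Nf1 (up to 0.0975, 0.0971 and 0.166).

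Between tissue and glioma cells, 4298 of 25398 genes were called by limma, 1986 higher and 2312 lower in the tissue, while on the unscaled table the higher share was 79.6% in place of 46.2%. The count was 1716 without glioma cell array 1, 2375 without glioma cell array 2 and 2813 without tissue array 2.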

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

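The test without astrocyte array 2 and neural stem cell array 1 together was chosen after seeing the data, and all other settings were planned. For glioma cells against astrocytes, leaving out 1 array gave 1987 to 4888 genes (4688 with all arrays). Against neural stem cells it gave 0 to 178 (244), for neural stem cells against astrocytes 1197 to 2660 (3633), and for tissue against glioma cells 1716 to 4669 (4298). Genes above both normal cell types numbered 0 to 84 (135) and genes below both 0 to 66 (61). A lone array is assumed to vary like the other groups, and fewer arrays leave fewer residual degrees of freedom. Without both doubted arrays the counts were 1689, 0, 0 and 4328, with 0 and 0 for the last pair. The zeros came with 1 residual degree of freedom, and limma then had 3378 and 7364 genes at an unadjusted p under 0.05 for glioma cells against neural stem cells and neural stem cells against astrocytes.

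No filter on dim probes gave 129 genes for glioma cells against neural stem cells, 73 above both normal cell types and 32 below both. The stricter filter gave 68, 40 and 19, and 2770 for tissue against glioma cells, with fewer genes tested. With all 9 arrays in the fit, 487 genes were called against neural stem cells and 160 lay below both. Apart from these, the arrays left out and the replicate block, no setting moved a count by more than 1.5 times. Scaling moved the median of all genes: on the unscaled table it was -0.29 for glioma cells against astrocytes (0.15 with scaling), -0.19 for neural stem cells against astrocytes (0.21) and 0.38 for tissue against glioma cells (-0.16).

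With the replicate number as a block, 5 genes were called for glioma cells against neural stem cells, 2601 for tissue against glioma cells, 5 above both normal cell types and 0 below both, and the neuron marker shift for neural stem cells against astrocytes was not called (adjusted p = 0.0622). The samples share only a number: same-numbered deviations correlated by -0.01 for glioma cells and astrocytes, 0.05 for glioma and neural stem cells, 0.12 for astrocytes and neural stem cells, and -0.0015 and -0.16 for tissue and glioma cells. A slide or scan block was not run, since slide and group cannot be told apart.

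Over the planned settings, 3702 named-gene values kept direction and side of the threshold, 476 lost the call, 47 gained it and 24 changed direction, none of these a called gene. Of list shifts, by the direction of the camera test, 780 kept both, 34 lost the call and 1 changed direction. Among those that lost the call, 2 medians also changed sign for neural stem cells against astrocytes: that of Hox genes was 0.087 with normexp (-0.56 otherwise), and that of astrocyte markers 0.29 without neural stem cell array 2 (-0.83). The minimum fold does not enter the list test. The other changes of direction are given next, and the cause of none was tested. With normexp, Slc4a1 was at 0.15 (glioma cells against astrocytes) and 0.11 (neural stem cells against astrocytes). On the unscaled table Nf1 was at -0.35 and -0.23 in these comparisons, Hba-a1 at -0.34 in the first, Slc4a1 at -0.010 for glioma cells against neural stem cells, and Trp53 at 0.47 for tissue. With 1 array left out, log2 fold changes for glioma cells against astrocytes ran from -0.55 to 0.12 (Slc4a1), -0.62 to 0.82 (Hba-a1), -0.91 to 0.19 (Trp53) and -0.16 to 0.34 (Nf1). Against neural stem cells they ran from -0.31 to 0.36 (Slc4a1, -0.14 without neural stem cell array 1), -0.64 to 0.038 (Trp53), -0.22 to 0.042 (Nf1), -0.25 to 0.99 (Ezh2), -0.19 to 3.71 (Mcm5) and -0.27 to 2.82 (median of the cell cycle list). The lowest values of the last 3 came without neural stem cell array 1. For neural stem cells against astrocytes the ranges were -1.10 to 6.03 (Ddx3y), -0.069 to 0.43 (Nf1) and -0.61 to 0.73 (Trp53, with 0.50 and 0.18 between), where 6.03 and 0.73 came without both doubted arrays. For tissue against glioma cells they were -0.43 to 0.26 (Trp53, with 0.10 between) and -0.47 to 6.04 (Matn4). Of the named called genes, the call held in each fit with 1 array left out for 39 of 65, 0 of 21, 20 of 49 and 28 of 51 in the order of the comparisons above. Between 60.1% and 65.7% of spots were well above background, which limits the dim genes to bounds.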

Other observations

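Tests chosen only after the result was seen were those of array scaling for the microglia markers, and of EZH2 loss and of the size of a slide effect for the tissue pattern, and the single genes in these paragraphs were also chosen after their values were seen. The lowest signal among probes well above background lay between -5.75 and -4.97, depending on the array. Values in these paragraphs below that of their array are not measured levels, and differences from them are not measured sizes. Some stefin genes were brighter in glioma cells than in neural stem cells, and the family as a whole was not tested. Csta2 stood at 4.44 and 3.64 on the glioma cell arrays and at -4.25 and -4.23 in neural stem cells, Stfa2l1 at 0.80 and 0.07 against -7.75 and -7.15, and Cstdc5 at 2.33 and 1.53 against -5.90 and -5.06. Chil3, a chitinase-like protein of macrophages, followed with 3.87 and 1.53 against -6.59 and -7.02, while the microglia marker Cx3cr1 was at -5.99 and -6.83 in the glioma cells.

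Replicates also differed among themselves. Gfap was at 1.85 on neural stem cell array 1 and -6.07 on array 2, Apoe at 8.39 and 2.66, and Mki67 at 3.03 and 6.09. Col1a2 was at -0.78 on astrocyte array 1 and 6.94 on array 2, and Dcn at -0.79 and 6.71. Irf7 was at 6.20 on tissue array 2 and at 0.85 and 0.04 on the other tissue arrays. Xist, expressed from the inactive X chromosome, was at 0.40 on tissue array 1 and at -7.39 and -7.56 on the others. The Y-linked Ddx3y was at -7.27 on tissue array 1 and at 0.29 and -1.57 on the others. Tissue array 1 was therefore not a repeat of the same RNA as the other tissue arrays. The mean level of the sex-linked list was -4.46 on astrocyte array 1 and -0.36 on astrocyte array 2. For neural stem cells against astrocytes, the log2 fold change of Ddx3y was 2.46 with all arrays and -1.10 without astrocyte array 1. The astrocyte arrays were therefore not repeats of the same RNA either. On both neural stem cell arrays Xist (1.87 and 1.11) and Ddx3y (0.24 and 0.26) were bright. The mean level of the sex-linked list was 0.22 and -0.17 there, against -4.51 and -4.44 on the glioma cell arrays. Between these groups its shift was not called (camera adjusted p = 0.0591, or adjusted p = 0.579 with an estimated correlation). Adjusted over the list alone, 2 of 4 members were lower in glioma cells.

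Microglia and macrophage markers were lower in glioma cells than in astrocytes. Array scaling is argued against as the whole cause, since the highest median log2 fold change of the list under the other scalings and background was -5.21. RNA of microglia or macrophages in the astrocyte samples is a candidate explanation: of 18 further myeloid genes that are on none of the marker lists, 15 were lower in glioma cells and well above background on both astrocyte arrays, among them Cyba at 4.42 and Fcer1g at 4.73 in the astrocyte mean. Of the same 18 genes, 16 were lower in neural stem cells than in astrocytes, so this candidate also bears on that contrast. No sort that would remove microglia or macrophages is described in the labels, and expression of these genes by the astrocytes themselves stays open and untested.

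Markers of microglia, vessels, neurons and astrocytes were higher in the EZH2-KO tissue than in glioma cells. RNA of host cells in the tissue may account for this, as 16 of 23 further vessel and neuron genes were also higher. The test of the size of a slide effect first took the 4 marker lists together, which left that explanation open, and was divided by list after its values were seen. Bootstrap intervals in this paragraph resampled the members of a list, not arrays, so they leave out the spread between arrays. Spike-in differences are the mean of the tissue arrays minus the mean of all 6 cell arrays. The probe with the largest difference, 1.82, was at 1.56, 0.58 and 0.13 in the tissue. In the glioma cells it was at -1.60 and -1.55, so against these alone its difference is larger. A difference in signal response between the slides, of the size seen in the spike-ins, is argued against as the whole rise of microglia markers. With glioma cell values raised to the floor their median rise was 6.19 (bootstrap interval 4.59 to 9.10), above these spike-in differences. For vessel, neuron and astrocyte markers, whose lowest median rise was 3.08, bootstrap intervals began at 1.76, 1.06 and 0.90. A slide difference as their whole rise therefore stays open, and as a part of the size it stays open throughout. After scaling, all 8 spike-in probes were higher on the tissue slide, by 0.65 to 1.82 on the log2 scale with a median of 1.63. That common shift is more than the 2-fold change a call needs, but the genes as a whole did not share it. Scaling takes off a shift that all probes share, and the median log2 fold change of all genes was -0.16. The spike-in shift therefore does not give the size of a slide effect on genes. A spike-in probe also deviated by 0.977 from it, between the values of 0.5 and 1 set beforehand. For loss of EZH2 acting on its targets, the 37 tested Hox genes and other Polycomb targets had a median of -1.32 (-0.83 with values raised to the floor), below the bound of -1 first written for excluding it; a bootstrap interval of -2.38 to -0.48 was then required to lie below that bound too, a rule added after the median was seen, so that this test leaves the explanation open. Genotype goes with tissue and slide here, so they cannot be told apart.

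Sox2, a transcription factor of neural stem cells, was at 2.28 on glioma cell array 2 and was not well above background on array 1. Its signal there, -7.55, lay below the lowest signal among probes well above background on that array, -5.28. Loss of the whole region within 1 Mb is argued against, because 17 neighbouring probes there had a median difference of -0.13, but a smaller loss was not tested and stays open: among the 17, 3 unnamed probes differed by -2.34, -2.33 and -1.66, and Sox2ot, the transcript that overlaps Sox2, by -1.28. A failed probe or spot stays open and could not be tested, since no other probe of Sox2 was among those kept. Apart from the loss of the region, no biological explanation was tested, because the design names none within a group.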
